A study of Drosophila melanogaster with 6 samples.

How the data were processed

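Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on S2 cells, an embryo-derived cell line of Drosophila melanogaster, with antibodies against hrp36 and hrp48. Both are heterogeneous nuclear ribonucleoproteins (hnRNPs), a class of proteins that bind nascent and mature RNA. Per the labels' protocols, fixation was in 1.8% formaldehyde and lasted 10 minutes, after which chromatin was sheared by sonication. The 6 samples comprised 2 hrp36 immunoprecipitates, 2 hrp48 immunoprecipitates and 2 inputs, each input being 10% of the chromatin. The titles number the ChIPs 1 and 2, and each number is shared by an input, an hrp36 and an hrp48 sample.

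The authors deposited 1 peak list per antibody, and the labels assign both lists to all 6 samples. Each list has 4 columns with no header, which hold the sequence name, the start, the end and a running peak name of the form that MACS writes. Per the submitters' processing notes, Bowtie2 2.2.2, MACS 1.4.2 and the genome build dm3 (Release 5) were used, and the notes as available here give no role or settings for the tools. Whether replicates were pooled before peak calling, and which input served as control, is not given in the sources used here. The lists carry no score, fold enrichment, p-value or read count per peak, so a peak is either listed or not. Read depth is therefore unknown here, and the lists give no value per replicate. The reads of the 6 samples were not used here.

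Because each antibody is represented by a single list, the spread between replicates could not be measured. All p-values below treat peaks as the units and compare these 2 lists, not conditions. Peaks that lie close together are not independent. Peaks merged within 10 kb were therefore tried for the overlap, the share outside the arms, the proximal share of each list and its difference between lists, the location of list-only peaks and the density, but not for the other tests. Exact (Clopper-Pearson) 95% intervals on shares of peaks cover the number of peaks only.

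Starts were read as counted from 0, as in BED files, and printed coordinates were converted to count from 1. Sequences were put in 3 classes by name: the arms (2L, 2R, 3L, 3R, 4 and X), the heterochromatic sequences (names ending in Het) and the unplaced sequences (U and Uextra). U and Uextra join scaffolds with no known position end to end, so distances along them have no chromosomal meaning. A peak was called shared when at least 1 bp overlapped a peak of the other list, and list-only otherwise. Overlap was compared with 10000 random placements of the hrp48 peaks on their own sequences. Clustering, the share of peaks with another peak of the same list within 10 kb, was compared with 10000 random placements of the same list. Placed peaks were allowed to overlap one another. Placement p-values are one-sided and cannot fall below 0.0001.

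Chromosome lengths of dm3 were not used here, so each sequence was taken to run from base 1 to the largest peak end in either list. Densities per Mb of this extent are upper bounds. Shares were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 13 sequences where each was tested. The centromere-proximal 10% of the arms 2L, 2R, 3L, 3R and X was compared with a uniform spread by two-sided exact binomial tests. The centromere lies at the high-coordinate end of 2L, 3L and X and at the low-coordinate end of 2R and 3R. Median widths were compared by two-sided permutation tests with 100000 resamples.

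Groups, the planned tests and 27 of the 60 alternatives were fixed before the data were examined, and 33 alternatives were added later. The rule for naming regions, also fixed then, took the 10 peaks with the highest score in each list or, with no score, the 10 widest. It also took the 10 densest windows of 100 kb over both lists together, and the peaks of chromosome 4 and the Het sequences as counts. Several planned steps could not be run. The comparison of scores and the stricter score threshold had no score to use. The test against chromosome length and the annotation of peaks to genes needed lengths and gene models of dm3, and the gene table at hand was of Release 6. Coordinates were not converted between builds, so no gene is named. In place of the score threshold, the upper 50% of each list by width was used, as an alternative added after seeing the data. Peak densities and the counts without 2L at 21.5 to 21.8 Mb, the 3 densest windows of the arms, were also added then. The location of list-only peaks was planned as an alternative to the share outside the arms and was made a result of its own afterwards. Leaving out Uextra was planned for that share and added for the overlap, the chromosome distribution and the location of list-only peaks. The other alternatives were overlaps of 50% of the shorter peak, of 50% of both peaks or within 1 kb, circular shifts, arms only and peaks merged within 10 kb. Further ones were proximal parts of 5% and 20%, and clustering distances of 1 kb and 50 kb.

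The overlap and clustering tests were checked in 100 runs on simulated lists with the real widths and sequences. The median width test was checked in 100 runs on widths drawn from the hrp36 list, split as the hrp36-only and hrp48-only peaks were. These runs used fewer placements and resamples than the tests themselves, and the Fisher and binomial tests were not checked. With no planted effect, the overlap test gave p under 0.05 in 3% of runs, the clustering test in 0% and the median width test in 8%. With 10 percent of the peaks planted as shared or as neighbours, or the widths of 1 set doubled, each of these tests gave p under 0.05 in 100% of runs. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.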

Results

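Chromatin occupancy of the RNA-binding proteins hrp36 and hrp48 was profiled by ChIP-seq in S2 cells, with 2 immunoprecipitates per protein and 2 inputs. The hrp36 list held 1020 peaks covering 2718 kb of dm3, and the hrp48 list held 938 peaks covering 2548 kb. Median peak width was 1437 bp for hrp36 (interquartile range 1225 to 2937 bp) and 1439 bp for hrp48 (1213 to 3337 bp). With a single list per antibody, no value below carries a replicate error. The series title concerns heterochromatin-associated RNA, and the comparisons address where along arms and heterochromatin each protein was found and whether both proteins were found at the same places.

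The hrp36 and hrp48 peak lists largely overlapped. The overlap by itself does not show joint binding, since no control or input peak list was at hand. Of the hrp36 peaks, 838 of 1020 (82.2%, 95% interval 79.7 to 84.5%) overlapped an hrp48 peak, and 838 of 938 hrp48 peaks (89.3%, 87.2 to 91.2%) overlapped an hrp36 peak. Shared sites were found on every sequence that held peaks, from 2 each on chromosome 4 and 2LHet to 500 on Uextra. The borders of the 839 overlapping pairs differed by a median of 21 bp (interquartile range 7 to 50 bp), and 88.9% of borders lay within 100 bp of each other. Most pairs (579) were on unplaced sequence, with a median of 16 bp and 92.7% within 100 bp. The 199 pairs of the arms had a median of 36 bp and 79.9% within 100 bp. In base pairs, the overlap made up 82.8% of the hrp36 and 88.4% of the hrp48 coverage. Random placement of the hrp48 peaks gave a median of 42 overlapped peaks and at most 69 in 10000 placements (permutation p = 0.0001, the smallest this number of placements can give). On the arms alone, 198 of 218 hrp48 peaks (90.8%) but only 198 of 346 hrp36 peaks (57.2%) were shared, against a median of 6 by random placement. Without Uextra the shared part was 338 of 495 hrp36 peaks (68.3%) and 338 of 379 hrp48 peaks (89.2%).

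By number, most peaks of both proteins lay outside the arms. Heterochromatic and unplaced sequences held 674 hrp36 peaks (66.1%, 63.1 to 69.0%) and 720 hrp48 peaks (76.8%, 73.9 to 79.4%). Many of these peaks were narrow, and in base pairs the arms held 1503 of 2718 kb of hrp36 coverage and 1249.6 of 2548 kb of hrp48 coverage. Among the upper 50% of each list by width, 46.9% of hrp36 and 54.6% of hrp48 peaks lay outside the arms. Uextra alone, which collects scaffolds with no chromosomal position, held 525 hrp36 and 559 hrp48 peaks, and U held 83 and 84. The mapped heterochromatic sequences held 66 hrp36 and 77 hrp48 peaks. Among these, 2RHet had 24 and 25 peaks, 3RHet had 21 and 25, 3LHet had 16 and 20, 2LHet had 2 and 4, and YHet had 3 and 3, for hrp36 and hrp48 respectively.

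Peaks were denser on mapped heterochromatic sequence than on the arms for both proteins. hrp36 had 7.45 peaks per Mb of extent on heterochromatic sequence (exact Poisson 95% interval 5.77 to 9.48) and 2.90 on the arms (2.60 to 3.22). hrp48 had 8.70 (6.86 to 10.9) and 1.82 (1.59 to 2.08). The ratio of heterochromatic to arm density was 2.57 for hrp36 (exact binomial p = 2.72e-10) and 4.77 for hrp48 (exact binomial p = 1.59e-24). On unplaced sequence the densities were 15.7 peaks per Mb for hrp36 and 16.6 for hrp48. With peaks merged within 10 kb, the ratio of heterochromatic to arm density was 2.30 for hrp36 and 3.81 for hrp48. These densities were computed after the lists had been seen. Extents end at the last peak, and a sequence with no peak in either list adds nothing to them.

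The share of peaks on heterochromatic and unplaced sequence was 10.7 percentage points higher in the hrp48 list than in the hrp36 list (Fisher's exact test, p = 1.95e-07). In counts, the hrp36 and hrp48 lists held 674 and 720 peaks there, and 346 and 218 on the arms. The higher hrp48 share thus came mainly from fewer hrp48 peaks on the arms. The lists have most peaks in common, so this test does not compare independent sets. Without Uextra the shares were 30.1% for hrp36 and 42.5% for hrp48 (Fisher's exact test, p = 0.000202). Of the 13 sequences, 3 differed in their share of the lists after adjustment. Uextra held more of the hrp48 list (59.6% against 51.5%, Fisher's exact test, adjusted p = 0.00421). The arms 3R (6.86% of hrp36 peaks against 3.62% of hrp48 peaks, Fisher's exact test, adjusted p = 0.0108) and 3L (6.57% against 3.84%, adjusted p = 0.0354) held more of the hrp36 list. None of the sequences passed when Uextra was left out, where 2 did at unadjusted p under 0.05 by Fisher's exact test. Among the upper 50% of each list by width, 0 passed with or without adjustment.

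**Figure D1:**
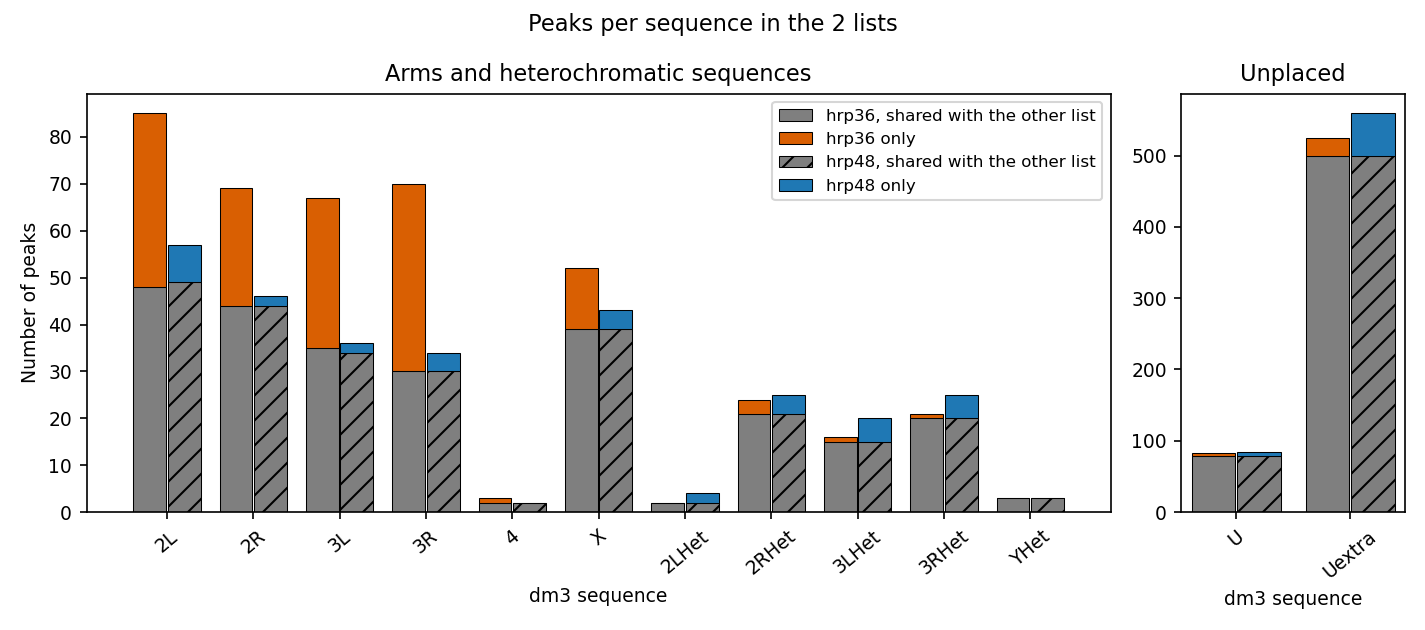
Number of peaks (y axis) on each dm3 sequence (x axis) in the hrp36 list (left bar of each pair) and the hrp48 list (right, hatched bar), split into shared (grey) and list-only (coloured) peaks. The right panel has its own scale. The 148 hrp36-only peaks of the arms stand against 20 hrp48-only peaks there, and 500 sites of Uextra were shared.

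The peaks that were in a single list lay in different parts of the genome for the 2 proteins. Of 182 hrp36-only peaks, 148 were on the arms (81.3%, 74.9 to 86.7%), with 40 on 3R, 37 on 2L, 32 on 3L, 25 on 2R, 13 on X and 1 on chromosome 4. Of 100 hrp48-only peaks, 20 were on the arms (20%, 12.7 to 29.2%), while 59 were on Uextra, 5 on U and 16 on heterochromatic sequences. The difference was 61.3 percentage points (Fisher's exact test, p = 2.76e-24). It was 45.5 percentage points without Uextra (Fisher's exact test, p = 1.22e-10). Among peaks of at least 2 kb it was 30.8 percentage points (53 of 58 against 20 of 33 on the arms, Fisher's exact test, p = 0.000732).

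On the arms, hrp36-only peaks were narrow. Their median width was 1506 bp (interquartile range 1246 to 2501 bp), against 5855 bp (4274 to 7889 bp) for shared hrp36 peaks there (permutation test, p = 1e-05, the smallest possible). Of the 148, 95 were under 2 kb wide, against 17 of 198 shared peaks. The 20 hrp48-only peaks of the arms had a median of 4522 bp, and none was under 2 kb. They did not differ detectably from shared hrp48 peaks of the arms, whose median was 5757 bp (permutation test, p = 0.15). Over all sequences together, the difference between shared and list-only widths was 8 bp for hrp36 (permutation test, p = 0.91). For hrp48 it was 241 bp (permutation test, p = 0.04), and 196 bp, no longer past the threshold, when sharing required overlap of 50% of both peaks (permutation test, p = 0.066). This pooled comparison mixes wide arm peaks with unplaced peaks, whose median width was 1319 bp in the hrp36 list and 1305 bp in the hrp48 list. On heterochromatic and unplaced sequence alone, shared hrp48 peaks were wider by a median of 195 bp than hrp48-only peaks (permutation test, p = 9e-05). For hrp36 the difference there was 78 bp (permutation test, p = 0.16).

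**Figure D2:**
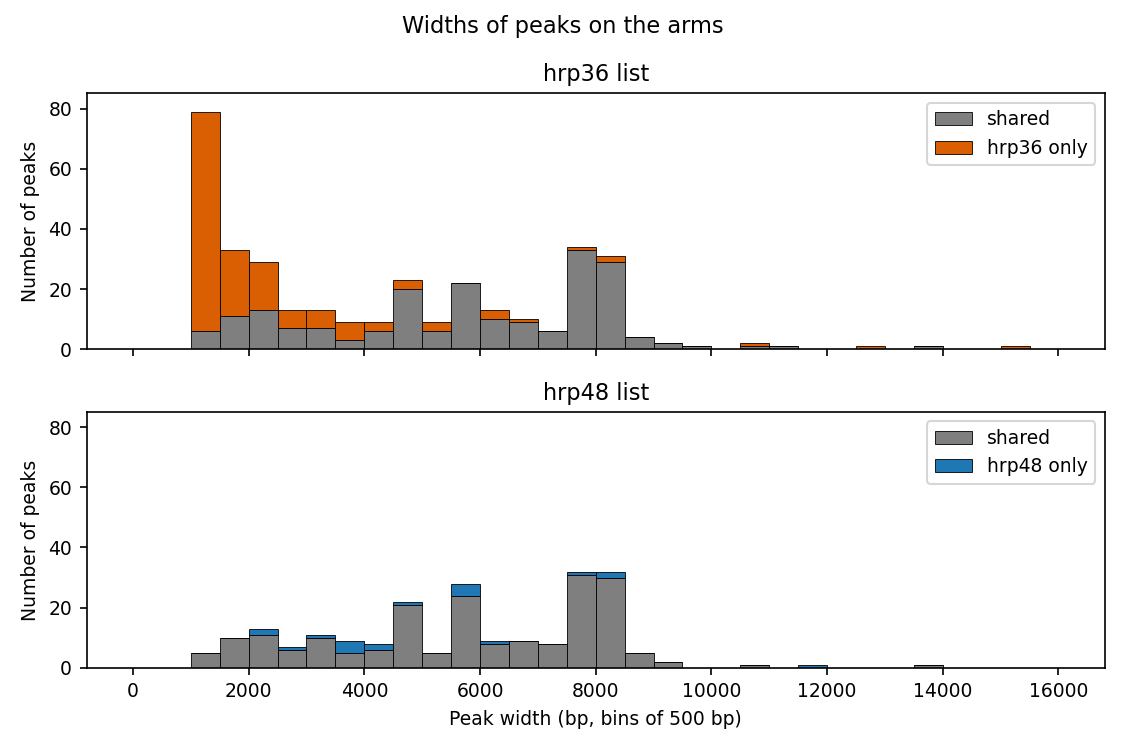
Distribution of peak widths (x axis, bp, bins of 500 bp) on the arms, as the number of peaks (y axis) that were shared (grey) or in a single list (coloured), for hrp36 (top) and hrp48 (bottom). hrp36-only peaks gather at the narrow end with a median of 1506 bp, while shared hrp36 peaks have a median of 5855 bp.

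Within the arms, both proteins were found more often near the centromere. In the centromere-proximal 10% of the 5 long arms lay 83 of 343 hrp36 peaks (24.2%, 19.8 to 29.1%; exact binomial test, p = 3.39e-14) and 64 of 216 hrp48 peaks (29.6%, 23.6 to 36.2%; exact binomial test, p = 9e-16). The shares were highest on 2L for hrp36 (29 of 85 peaks, 34.1%) and on 2R for hrp48 (17 of 46 peaks, 37.0%). On 2L, 19 hrp36 and 12 hrp48 peaks lay from 21.5 to 21.8 Mb, within its proximal 10%. Without them the shares over the 5 arms were 19.8% for hrp36 (64 of 324) and 25.5% for hrp48 (52 of 204). The test of 2L by itself was not repeated without them. Of the long arms, only 3R did not pass after adjustment over 10 tests, with 12.9% for hrp36 (exact binomial, adjusted p = 0.423) and 20.6% for hrp48 (exact binomial, adjusted p = 0.0844). The 2 proteins did not differ detectably in this share (difference 5.43 percentage points, Fisher's exact test, p = 0.168). Since 196 of these peaks in each list were shared, this test does not compare independent sets. Shared hrp36 peaks were proximal more often (58 of 196, 29.6%) than hrp36-only peaks (25 of 147, 17.0%; Fisher's exact test, p = 0.00752). Without 2L from 21.5 to 21.8 Mb the shares were 26.2% and 10.9% (Fisher's exact test, p = 0.000649). Of the hrp36-only peaks under 2 kb, 10 of 94 were proximal (10.6%, 5.22 to 18.7%), a share that did not differ detectably from a uniform spread (exact binomial test, p = 0.863).

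**Figure D3:**
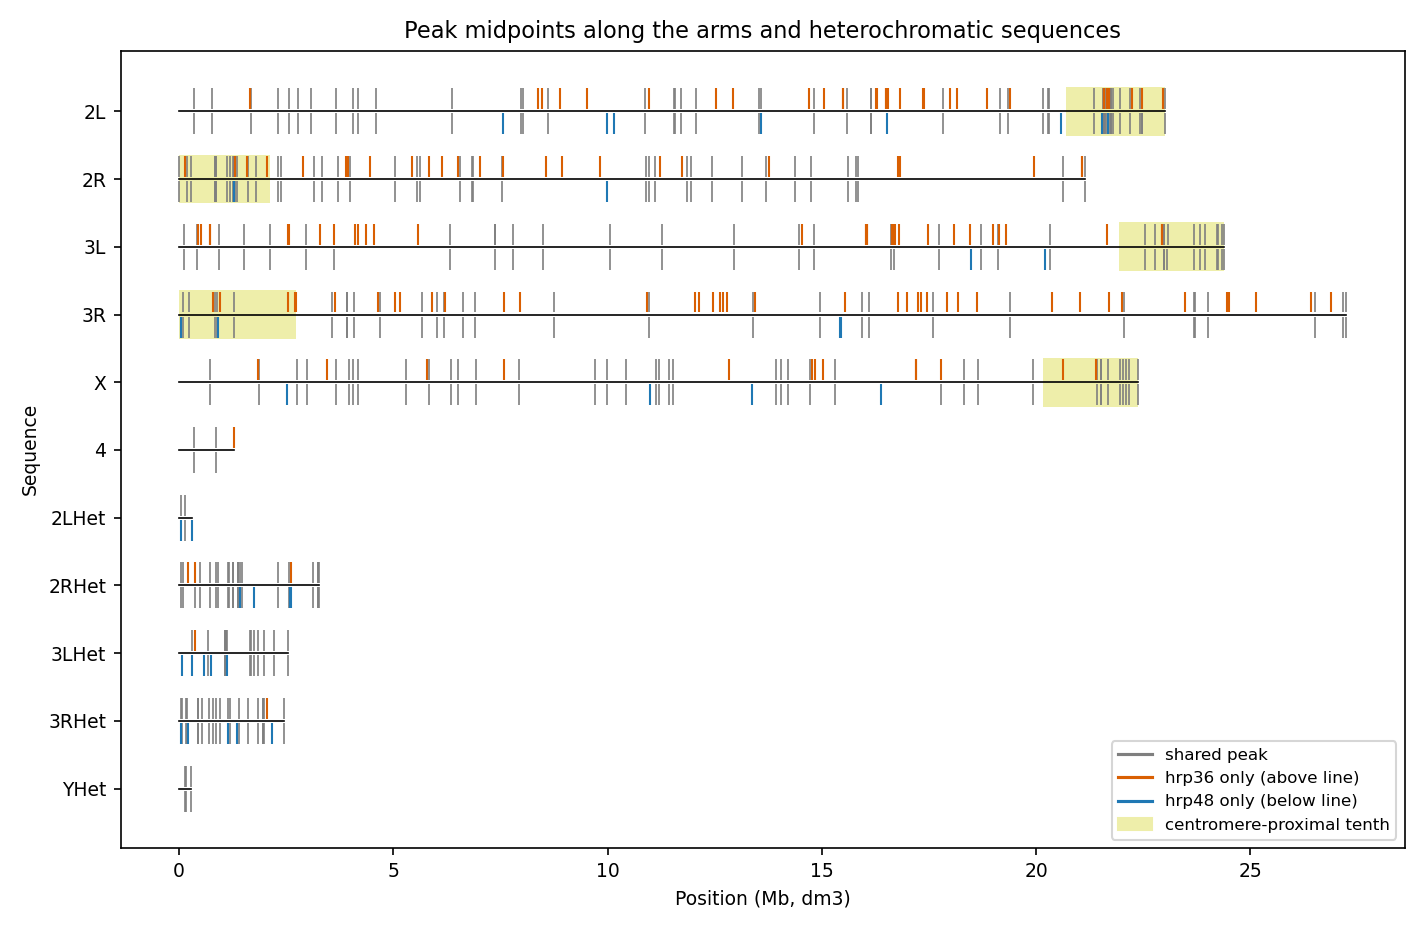
Midpoints of peaks (ticks) along the arms and heterochromatic sequences of dm3 (x axis, Mb; y axis, sequence), with hrp36 above and hrp48 below each line, grey for shared and coloured for list-only peaks. Shading marks the centromere-proximal 10% of the long arms, which held 24.2% of hrp36 and 29.6% of hrp48 peaks of those arms.

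The 10 densest windows of 100 kb held 10 to 14 peaks over both lists, and 8 of them were on unplaced sequence (5 on Uextra and 3 on U). The other 2 were neighbours on 2L, from 21.5 to 21.7 Mb. There the window from 21.6 Mb held 8 hrp36 peaks covering 48.8 kb and 4 hrp48 peaks covering 19.3 kb, with 6 hrp36-only peaks and 1 hrp48-only peak. The window from 21.5 Mb held 6 hrp36 and 4 hrp48 peaks. In the unplaced windows nearly all peaks were shared, as in Uextra from 13.4 to 13.5 Mb with 7 peaks in each list and none in a single list.

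The widest peaks were mostly shared, with 7 of the 10 widest hrp36 peaks and 8 of the 10 widest hrp48 peaks overlapping the other list. The widest shared site was on 2L, listed at 22424695 to 22438206 for hrp36 (13512 bp) and at 22424700 to 22438357 for hrp48 (13658 bp). Another was on 3RHet, at 58330 to 70702 for hrp36 and 58339 to 70688 for hrp48. A further one was on 2RHet, at 1143698 to 1155750 for hrp36 and 1143664 to 1155724 for hrp48. The widest peak of all was hrp36-only, on 2R at 6509627 to 6524879 (15253 bp). A further 2 of the 10 widest hrp36 peaks had no hrp48 counterpart, on 2L at 21678767 to 21691579 and on X at 21405144 to 21415688. The widest hrp48-only peak was on 2L at 13574818 to 13586412 (11595 bp), and the other was on 3RHet at 192738 to 201714 (8977 bp). Chromosome 4, a small and largely heterochromatic chromosome, had 3 hrp36 and 2 hrp48 peaks. Both hrp48 peaks, at 340285 to 349077 and at 860344 to 862571, were shared, and the third hrp36 peak lay at 1287178 to 1288380.

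On the arms, a setting added after the lists had been seen, peaks lay closer together than random placement gave. There, 19.1% of hrp36 peaks had another hrp36 peak within 10 kb, against a median of 8.09% by placement (permutation p = 0.0001, the smallest possible). For hrp48 it was 12.8% against 5.50% (permutation p = 0.003). Without 2L from 21.5 to 21.8 Mb the shares were 15.0% (permutation p = 0.0005) and 10.7% (permutation p = 0.0186). Over all sequences, as planned, the shares were 26.5% against 22.9% for hrp36 (permutation p = 0.017) and 28.4% against 26.0% for hrp48 (permutation p = 0.0951), the latter not past the threshold. Within 1 kb, neither list held more neighbours than placement gave. Placed peaks could overlap one another and listed peaks could not, so this comparison does not show that close neighbours are lacking.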

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

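The test of the location of list-only peaks and those of the overlap by random placement and circular shift were planned, and the other tests in this part were chosen after the lists had been seen.

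The location of list-only peaks differed between the proteins. The share on the arms was 61.3 percentage points higher among hrp36-only than among hrp48-only peaks (148 of 182 against 20 of 100, Fisher's exact test, p = 2.76e-24). Their widths on the arms differed too, with a median 3016 bp larger for the 20 hrp48-only than for the 148 hrp36-only peaks (4522 against 1506 bp, permutation test, p = 2e-05).

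Several readings of the hrp36-only peaks on the arms were weighed. Shared peaks split or shifted at their borders would put most of them beside an hrp48 peak, but 4.05% (6 of 148, interval 1.50 to 8.61%) lay within 1 kb of one. A looser effective threshold over the whole hrp36 list could give hrp36 the majority of list-only peaks elsewhere as well. On heterochromatic and unplaced sequence it held 29.8% of them (34 of 114, interval 21.6 to 39.1%). These counts are the rest of the comparison that flagged the arm peaks, so they are not separate evidence. Nor is it known how extra weak calls would spread over the sequences, so a looser threshold is not excluded. What stays open is whether hrp36 occupies more arm sites or whether its antibody, background, enrichment, depth or threshold differed. These cannot be told apart with 1 list per antibody and no value per peak.

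The large overlap was also weighed. Random placement reached at most 69 overlapped hrp48 peaks, against 838 observed, which argues against chance placement within sequences. Circular shifts, which keep the spacing of peaks, gave a median of 42 and at most 516. Shifts were drawn from the whole extent, and a shift near 0 can restore the true overlaps of a sequence, so the highest value is not a ceiling for chance. Multi-copy sequence that any antibody or background recovers could give such overlap. It would raise the shared part outside the arms only if shared arm peaks were not multi-copy themselves. The shared part was 37.7 percentage points higher outside the arms for hrp36 (Fisher's exact test, p = 2.05e-48) but -1.94 points for hrp48 (Fisher's exact test, p = 0.455). The hrp36 value restates the hrp36-only arm peaks. These values cannot decide the question, since shared arm peaks may be repeat copies, as the recurring widths described below leave open. A background common to both antibodies and joint binding by both proteins cannot be told apart, since 0 control or input peak lists were at hand.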

How the results depend on the processing

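Of 60 alternatives to 13 results, 47 kept the direction and the side of the threshold, or the count within 1.5 times. Of the 60, 33 were chosen after seeing the data: those by width, without 2L from 21.5 to 21.8 Mb, without U and Uextra, the width tests by sequence class, the clustering on the arms, those on density and on the location of list-only peaks, and those without Uextra except for the share outside the arms. Under every alternative run, the overlap, the higher hrp48 share outside the arms, the proximal excess of each list, the location of list-only peaks and the density ratios kept their calls. The overlap ranged from 85.1 to 91.4% of hrp48 peaks, and circular shifts reached at most 516 overlapped peaks with a median of 42. The number of sequences whose share differed was 3, but 7 with list-only peaks, 0 with the upper 50% by width (0 at unadjusted p under 0.05) and 0 without Uextra (2 at unadjusted p under 0.05), all by Fisher's exact test on fewer peaks. For hrp36 widths, shared minus list-only, the 8 bp became 4349 bp on the arms (permutation test, p = 1e-05) and turned to -50 bp with overlap of 50% of both peaks (permutation test, p = 0.41), neither this nor the 8 bp past the threshold. For hrp48, the 241 bp lost its call as 196 bp with overlap of 50% of both peaks (permutation test, p = 0.066) and as 1235 bp on the arms (permutation test, p = 0.15, 20 list-only peaks), while on heterochromatic and unplaced sequence it was 195 bp with its call kept (permutation test, p = 9e-05). Clustering turned in both lists at a distance of 1 kb, where placed peaks could overlap and listed peaks could not. It was 5.69% of hrp36 peaks against a placement median of 6.18% (permutation p = 0.705) and 4.26% of hrp48 peaks against 7.04% (permutation p = 0.995). Clustering of hrp48 passed the threshold at 50 kb (68.8%, permutation p = 0.0285), in the upper 50% by width (16.4%, p = 0.0009 by permutation), on the arms (12.8%) and on the arms without 2L from 21.5 to 21.8 Mb (10.7%). No paired analysis was possible because the lists hold no value per sample, and no replicate could be left out for the same reason. The planned score comparison, score threshold, length test and gene annotation were not run. Depth was unknown, so the absence of a peak from a list does not show that the protein was absent.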

Other observations

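The tests in this part were chosen after the lists had been seen.

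On 2L and 3L, hrp36 formed runs of peaks that the hrp48 list held in part or not at all. On 2L from 21.5 to 21.8 Mb, which takes in the 2 windows of 2L named by rule, there were 19 hrp36 peaks covering 108 kb and 12 hrp48 peaks covering 55.9 kb, with 10 hrp36-only and 2 hrp48-only peaks. On 3L from 16029743 to 16054961 there were 4 hrp36 peaks covering 9.69 kb, all 4 of them hrp36-only. On 3L from 16.6 to 16.7 Mb there were 5 hrp36 peaks covering 24.4 kb, 3 of them hrp36-only, and 2 hrp48 peaks covering 11.9 kb. Other dense windows of the arms went the other way. On 2R from 0.8 to 0.9 Mb, 4 hrp36 peaks covered 10.8 kb and 4 hrp48 peaks 20.45 kb. On 2L from 13.5 to 13.6 Mb, 2 hrp36 peaks covered 13.5 kb and 3 hrp48 peaks 25.6 kb. Of the latter, 1 was hrp48-only, the wide peak named above that lay within 1 kb of an hrp36 peak. These regions were picked for their values, and no test was made of them. On U, 69.9% of hrp36 peaks (58 of 83, exact binomial test, adjusted p = 0.00126 over 4 tests) and 69.0% of hrp48 peaks (58 of 84, adjusted p = 0.00126 by the same exact test) lay beyond the midpoint of its extent. On Uextra the shares were 45.0% (exact binomial test, adjusted p = 0.0309) and 46.2% (exact binomial test, adjusted p = 0.0756). Both sequences are scaffolds joined end to end, so these shares say nothing about chromosomal position. The 2 lists are also not separate evidence, since 79 peaks of each list on U and 500 on Uextra were shared.

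Widths of shared peaks on the arms recurred. Of 161 shared hrp36 peaks of 3 kb or more, 48 had widths from 7666 to 8166 bp and 24 had widths from 5370 to 5870 bp, together 44.7%. Only the count of the fuller range was tested on the arms, so an excess in the range with 24 peaks is not shown. Draws from a smoothed distribution of the same widths put a median of 22 and at most 34 peaks in their fullest 500 bp range, so a smooth spread does not give the 48 (permutation p = 0.0001, the smallest possible, also with kernels of 500 and 2000 bp in place of 1000 bp). Of 31 hrp36-only arm peaks of 3 kb or more, 3 fell in the 2 ranges (9.68%), but the ranges were chosen on the shared peaks. A candidate explanation is that many shared sites are full-length copies of dispersed repeats, such as retrotransposons, each family having a fixed length. The ranges found on the arms were then overfilled among shared heterochromatic peaks too, with 13 of 39 (33.3%) against a median of 6 in smoothed draws (permutation p = 0.0069), as the hypothesis requires. It remains untested against repeat annotation of dm3, which was not used here, and a repeat copy can also collect reads from its other copies.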
